A study of Drosophila melanogaster with 2 samples.

How the data were processed

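The data were peak lists from transcription factor ChIP-seq of whole Drosophila melanogaster embryos collected from 0 to 24 h, from a strain that expresses Ken fused to enhanced GFP. Ken, the product of ken and barbie, is a BTB zinc finger protein. Chromatin was sheared by sonication to 200 to 800 bp and precipitated with an antibody against GFP, per the description in the labels, while another field of the same labels names ken as the antibody. The series held 1 group with 2 biological replicates. A control experiment is named as possible in the labels and was not analysed here, so no level in unprecipitated or mock-precipitated chromatin stands beside the values. The sex of the embryos and the number of reads per library are not given in the sources used here.

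Each replicate had a ranked list of candidate peaks and a thresholded list, and both replicates together had 2 ranked and 2 thresholded lists, of which 1 was called conservative. The lists were ordered by the irreproducible discovery rate (IDR), a measure of how well the rank of a peak repeats between 2 sets of reads. All coordinates are on dm6, per the labels. The lists were derived from filtered alignments and from a further file not used here, per the deposited notes, and a further input went into each thresholded list, whose role is not given in the sources used here. The aligner, the peak caller and the 2 sets of reads compared within a single replicate are not given in the sources used here. The signal of each peak is the authors' value, deposited without a stated scale, and is used to rank or filter peaks, to compare medians within a list and, as log2, to compare the replicates. Whether its scale is the same in both replicates is not known, so log2 differences between them show which peaks differ from the rest and not how much more was recovered. The score is the deposited IDR score, capped at 1000. The ranked lists also hold the global IDR as −log10, deposited by the authors. Every peak of the conservative list had a −log10 global IDR of at least 2.001, a global IDR at or below 0.01, so the threshold was read from the values. In the ranked list of the conservative peaks 2194 candidates reached that level, and 107 of them were not in the conservative list. These 107 were left out of the main background. Comparisons over all ranked candidates included those of them on the main arms.

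The ranked list that belongs to each thresholded list was found from the identical coordinates and scores. The 2 ranked lists made from both replicates hold 16 further columns in all with values of single inputs, and no header ties them to a replicate, so these were not used. The signal of a replicate at a peak was taken from the ranked list of that replicate, as the signal of the nearest candidate summit within 200 bp. This departs from the planned source of the replicate signals. Neighbouring peaks can take the signal of the same candidate.

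Genes and transcription start sites (TSSs) came from Ensembl release 115 on the main chromosome arms 2L, 2R, 3L, 3R, X, 4 and Y, and sequence came from the release 6 assembly, which has dm6 coordinates. No peak ended beyond the length of its arm. Peaks on unplaced scaffolds were counted and entered no other comparison. Coordinates are printed from 1. Features were assigned to the summit base in the order 5' UTR, 3' UTR, coding exon, intron and intergenic, from protein-coding genes. The conservative list was the main list, and the background was the 146877 candidates on the main arms with a global IDR above 0.01.

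Replicate agreement was the share of thresholded peaks with a summit of the other replicate within 200 bp, with exact Clopper-Pearson 95% intervals and 1000 random placements within the same chromosome. Signals of the 2 replicates were compared across peaks with Spearman and Pearson coefficients and 100000 permutations, whose smallest possible p is 1e-05. Peaks are not independent replicates. Promoter share, chromosome arms, motifs, gene lists and replicate-specific peaks were tested with two-sided Fisher exact tests. A promoter peak had its summit within 500 bp of a protein-coding TSS. Motif matches were sought on either strand within 100 bp of the summit, against 5 background candidates per peak matched in bins of 5% GC. The density of matches within 50 bp of the summit was set against that from there to 250 bp with exact binomial tests. Words of 8 bp in windows of 101 bp at the summit were set against windows centred 250 bp away. Gene lists were tested among 12473 protein-coding genes with any candidate summit within 1000 bp of a TSS, and a gene is called bound when a conservative summit lay within that distance. Benjamini-Hochberg adjustment ran over the 16 motifs, the 27 gene lists, the arms or the words, with a threshold of 0.05. Odds ratios carry 95% intervals on the log scale. All p-values treat peaks or genes as independent and do not measure variation between embryo collections, because the series has 1 group. Neighbouring genes that share a promoter peak make the gene tests less exact than their p-values state.

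The comparisons, the 27 gene lists, the 16 motifs and the rule for named genes were fixed before the data were examined. The named genes were ken, Socs36E, vvl, trh and kni whatever their values, the genes at the 20 strongest conservative peaks, up to 4 bound members of each list by signal, and up to 5 conservative peaks with the largest difference of log2 signal between replicates. Of the genes under this rule, 1 is not reported here. List members were matched by symbol, older symbols through the synonyms of RefSeq, and 2 entries, Ipo-alpha3 and Trh, were not matched. Alternatives included the other thresholded list, each replicate alone, the stronger 50% of peaks, other windows, other backgrounds and other gene assignments. Added after seeing the data were a global IDR at or below 0.001, leaving out peaks within 500 bp of a stronger peak, within 50000 bp of ken or within 500 bp of a tRNA gene, the word CGATA, and 8 further gene lists.

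The tests were checked on simulated data. For motif enrichment and for central enrichment, 2 of 16 motifs were planted in 10% of random genomic windows, and both were recovered with 0 other calls. For words of 8 bp, 5 words planted in 3% of windows were recovered among 32862 tested, with 17 other calls, of which 16 shared 6 bases with a planted word. For gene lists, 5 of 30 lists with 60% bound members were recovered with 0 other calls. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.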

Results

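The series mapped where Ken, tagged with GFP, was recovered on chromatin of Drosophila embryos. Ken is a BTB zinc finger protein known as a repressor of a subset of JAK-STAT target genes. There was 1 group, embryos of 0 to 24 h, with 2 biological replicates. The thresholded lists held 1544 peaks in replicate 1 and 1819 in replicate 2. The conservative list from both replicates held 2087 peaks, 2031 of them on the main chromosome arms, and the other thresholded list held 2356. The ranked candidates numbered 137061 and 124478 in replicates 1 and 2. Read depth was unknown, and no control library was analysed here.

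Most of the strongest peaks lay at promoters. The highest signal, 1168, was 90 bp from a TSS of MESK2 on 2R at 21501804 to 21502183, with 486 in replicate 1 and 679 in replicate 2. The next was 252 bp from a TSS of Sox14, which encodes an HMG-box transcription factor, on 2R at 23978395 to 23978723, with a signal of 1157. Among the 20 strongest peaks, 18 lay within 500 bp of a TSS and all 20 were in the thresholded lists of both replicates. They included Rpn6, a subunit of the proteasome lid (signal 886, in an intron 105 bp from a TSS), Ube3a, an E3 ubiquitin ligase (868), RpL32, a protein of the large ribosomal subunit (842), and Capr, an RNA-binding protein (710, in the 5' UTR). Further ones were at CG11857, RhoGAP93B, Mic26-27 (a protein of the mitochondrial inner membrane complex), CalpA (a calpain protease), Creld, Pp2A-29B (the scaffold of protein phosphatase 2A), milt (an adaptor of mitochondrial transport), CG8613, EndoGI (an inhibitor of endonuclease G), Fit2, Daxx and mi, with signals from 689 down to 565. The 2 exceptions from promoters were Adf1, a transcription factor, with a summit in its intron 802 bp from a TSS (941), and org-1, a T-box factor. The org-1 peak lay in an intron on X at 8452197 to 8452545, 2496 bp from a TSS, with a signal of 895, 583 in replicate 1 and 305 in replicate 2. The 61 bp around its summit, X 8452343 to 8452403, read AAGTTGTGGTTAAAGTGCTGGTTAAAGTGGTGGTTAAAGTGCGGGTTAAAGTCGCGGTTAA, a tandem repeat.

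The genes named whatever their values differed. A conservative peak lay 17 bp from a TSS of ken itself (FBgn0011236), on 2R at 23870051 to 23870460, in sequence annotated as intergenic. Its signal was 214, with 103 in replicate 1 and 112 in replicate 2. The gene body, 23870273 to 23877442, held 3 more conservative summits. Socs36E (FBgn0041184), a negative regulator of JAK-STAT signalling, is not on the list of targets described as repressed by Ken. It had a peak in its 5' UTR on 2L at 18152075 to 18152484, 137 bp from a TSS. Its signal was 72.1, with 47.6 and 35.3 in replicates 1 and 2. The developmental factors vvl, trh and kni had 0 conservative peaks within 1000 bp of a TSS. Their nearest conservative summits were 37195, 30079 and 90859 bp from a TSS, and their highest candidates within 1000 bp reached 48.1, 48.0 and 38.7. Those candidates stood at the 96.1, 96.1 and 89.3 percentiles of the candidates that did not pass.

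The replicates placed most strong peaks at the same positions. Of the 1525 thresholded peaks of replicate 1 on the main arms, 1145 had a summit of replicate 2 within 200 bp, 75.1% (exact 95% interval 72.8 to 77.2). Of the 1738 of replicate 2, 1138 had a summit of replicate 1, 65.5% (63.2 to 67.7). Random placement gave 7.86 and 7.87 peaks on average and 18 at most in each case. Among the 25% of peaks with the highest signal 97.1% and 97.5% were shared, and among the lowest 25% it was 46.6% and 31.3%. Against the other replicate's candidates of any rank the shares were 93.05% and 96.26%, where random placement gave 32.5% and 36.2% on average, so these shares say less.

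Across the 1910 conservative peaks with a signal in both replicates, Spearman's rho was 0.71 and Pearson's r of log2 signal was 0.76, each with a permutation p of 1e-05, the smallest possible. These peaks had been selected for ranks that repeat, so neither value is independent of that selection. The log2 difference of the signals had an SD of 0.57 across peaks. Across 76863 candidates of any rank rho was 0.26. The largest differences were at CG12213, where replicate 1 had 176, replicate 2 had 31.9 and the conservative list 36.8, and at Acsx4 (158 and 33.1) and EcR (108 and 28.1), both higher in replicate 1. The 176 at CG12213 may belong to a stronger neighbour, because neighbouring peaks can take the same candidate, and this was not tested. Near ken, peaks with signals of 162.5 and 7.43 both took 70.2 from replicate 1. Replicate 2 was higher at Lap1 (157 against 42.5) and Mrgn1 (125 against 34.97). The EcR summit, in an intron of the gene for the ecdysone receptor, lay in the tRNA gene tRNA:Asn-GTT-1-3 on 2R at 6153506 to 6153579. The Acsx4 summit, intergenic, lay 7 bp from tRNA:Ala-AGC-2-11.

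**Figure D1:**
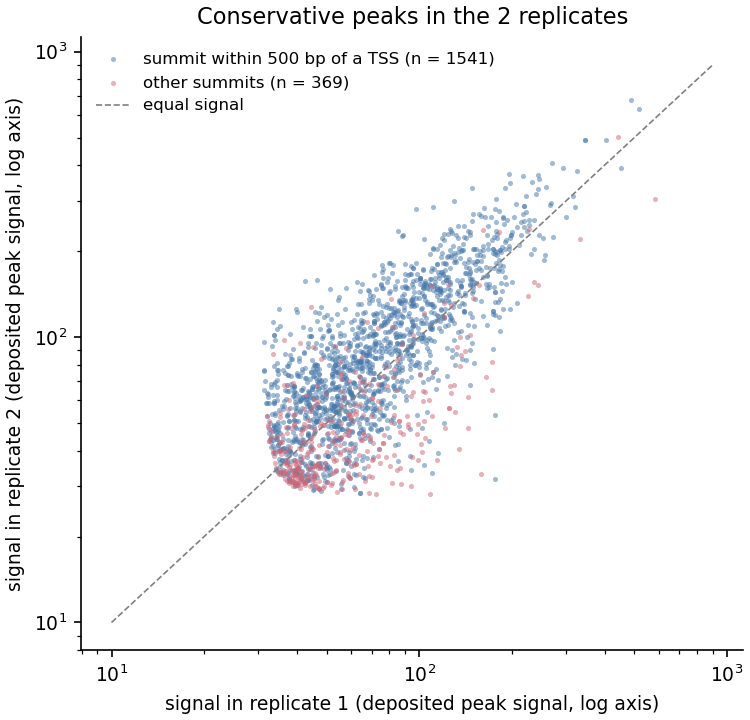
Deposited peak signal of each conservative peak in replicate 1 (horizontal, log axis) and replicate 2 (vertical, log axis), 1 point per peak, coloured by whether the summit lies within 500 bp of a TSS; the dashed line marks equal signal. Across the 1910 peaks rho was 0.71, and peaks over 500 bp from a TSS lie more to the replicate 1 side, with a median log2 difference of 0.30 against -0.26 nearer.

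Peaks thresholded in 1 replicate only were less often at promoters than shared ones. The groups were not matched for signal, and weak peaks were shared less often. In the stronger 50% of conservative peaks 90.6% were at promoters, against 80.6% of all. The contrasts below therefore cannot be told apart from those between weak and strong peaks. In replicate 1, 50.3% of the 380 unshared peaks were within 500 bp of a TSS, against 90.7% of the 1145 shared (odds ratio 0.103, interval 0.078 to 0.137, Fisher exact adjusted p = 1.27e-58). In replicate 2, 84.2% of 600 unshared peaks were, against 90.8% of 1138 shared (0.540, 0.401 to 0.727, exact adjusted p = 1.06e-04). The unshared peaks of the 2 replicates differed from each other in this share, with an odds ratio of 0.190 (exact p = 1.08e-29). Unshared peaks of replicate 1 lay within 500 bp of a tRNA gene in 66 of 380 cases, 17.4%, against 5 of 600 in replicate 2 (odds ratio 25.01, interval 9.97 to 62.7, exact p = 2.67e-23), a comparison chosen after the values were seen. The consensus of Ken from in vitro selection, GNGAAAK, was near 22.9% of unshared and 22.5% of shared peaks of replicate 1 (odds ratio 1.02, 0.774 to 1.35) and near 25.3% and 23.2% in replicate 2 (1.12, 0.893 to 1.41). The word CGATA, chosen after the data were seen, was near 45.3% of unshared and 84.7% of shared peaks of replicate 1 (0.149, exact adjusted p = 2.85e-48) and near 71.0% and 86.1% in replicate 2 (0.395, exact adjusted p = 1.81e-13). At promoters alone it was also less frequent in unshared peaks (0.182 and 0.359, exact p = 6.46e-20 and 3.39e-11), and over 500 bp from a TSS neither difference passed (0.734 and 0.744).

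Conservative peaks were concentrated at promoters. Their summits were within 500 bp of a protein-coding TSS in 1638 of 2031 cases, 80.6% (exact 95% interval 78.9 to 82.3), against 10.9% of the 146877 candidates that did not pass. The odds ratio was 34.0 (30.5 to 38.1), with an exact p too small to be represented. The median summit was 68 bp from a TSS, and 4097 bp among the candidates that did not pass. In gene models, 59.6% of summits were intergenic, 19.1% in a 5' UTR, 15.5% in an intron, 3.64% in a coding exon and 2.12% in a 3' UTR. Of the background 21.6% were in a coding exon and 40.4% in an intron, and both shares were lower among peaks (odds ratios 0.137 and 0.271, exact adjusted p = 1.12e-118 and 4.64e-129). Over 500 bp from a TSS the coding exon share was still lower (0.240, exact adjusted p = 6.73e-16), while the intron share, 42.2% against 42.7%, did not differ detectably (0.982, exact adjusted p = 0.878). The 3' UTR share was lower over all peaks (0.554, exact adjusted p = 5.91e-05) but higher there, 8.14% against 3.91% (2.18, exact adjusted p = 1.50e-04). The odds ratio moved by over 1.5 times in several alternatives: 62.8 in the list of replicate 2 alone, 53.4 with a window of 200 bp, 78.3 in the stronger 50% of peaks, 107 at a global IDR of 0.001, and 8.56 against the 2031 candidates just below the threshold, of which 32.7% were near a TSS.

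**Figure D2:**
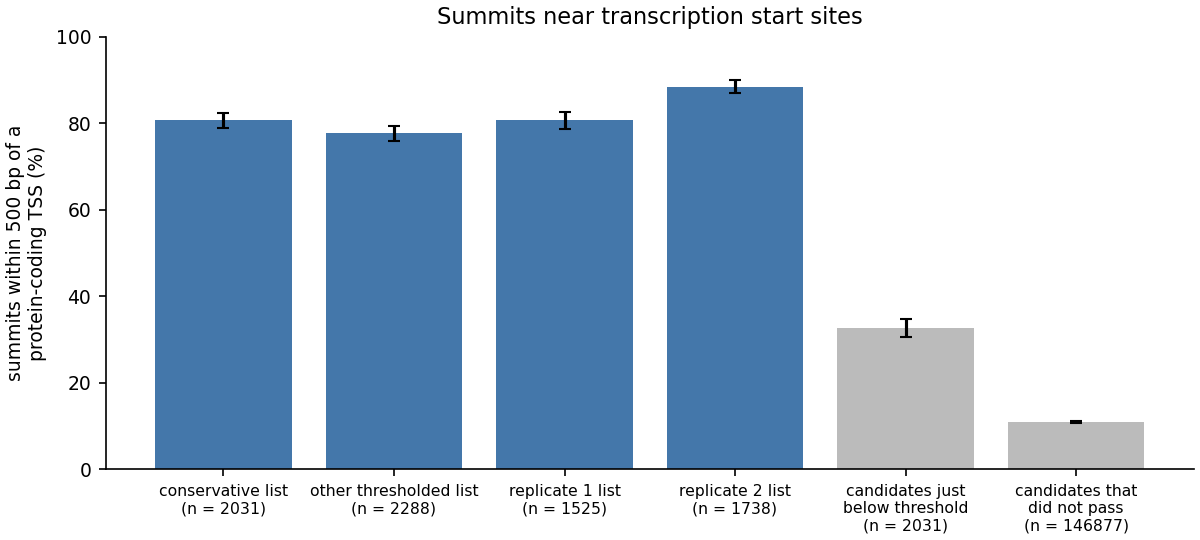
Share of summits within 500 bp of a protein-coding TSS (vertical axis, percent) in 4 thresholded lists (blue) and 2 sets of candidates below the threshold (grey), with exact 95% binomial intervals as error bars. The thresholded lists lie between 77.7% and 88.5%, the candidates at 32.7% and 10.9%.

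The peaks spread over the arms nearly as the candidates did. X held 432 peaks, 21.3%, against 17.4% of candidates (odds ratio 1.28, 1.15 to 1.42, Fisher exact adjusted p = 7.00e-05), and 2R held 21.9% against 18.9% (1.203, 1.08 to 1.34, exact adjusted p = 0.0020). Arms 3L (0.837, exact adjusted p = 0.0041) and 3R (0.882, exact adjusted p = 0.025) held fewer. On Y there were 0 peaks, which allows a share of up to 0.181%, and 734 candidates (exact adjusted p = 2.79e-04). Arms 2L (0.912) and 4 (0.786) did not pass. These counts leave out 56 conservative peaks on scaffolds, all of them assigned to X.

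Of the 16 motifs, the DNA replication-related element had the highest odds ratio, although most summits lacked its 8 bp word. TATCGATA, the site of the promoter factor DREF that the boundary protein BEAF-32 also recognises in part, lay within 100 bp of 598 of 2031 summits, 29.4%, against 0.83% of GC-matched candidates (odds ratio 50.03, 39.6 to 63.3, exact p too small to be represented). Motif 1, GGTCACACT, bound by the pausing factor M1BP, was near 4.28% against 0.20% (22.7, 13.9 to 37.0, exact adjusted p = 2.52e-48). The E-boxes CAGCTG (12.2% against 7.26%, odds ratio 1.78, exact adjusted p = 7.05e-12) and CACGTG (3.20% against 2.23%, 1.45, exact adjusted p = 0.0286) were also more frequent. The Ken consensus GNGAAAK was less frequent, 23.2% against 26.5% (0.841, 0.752 to 0.940, exact adjusted p = 0.0073), a call lost in the list of replicate 2 alone (0.894), within 50 bp (0.909), without GC matching (0.900) and with background matched for GC and TSS distance (0.8745). The site of Caudal and Abd-B (0.440, exact adjusted p = 4.73e-10) and the GATA site (0.617, exact adjusted p = 0.0428) were also less frequent. The remaining 9 motifs did not pass, among them the STAT92E sites with spacers of 3 and 4 bp (odds ratios 0.953, 0.776 to 1.17, and 0.992, 0.814 to 1.21). With background matched also for TSS distance, the odds ratio of TATCGATA was 14.4 and that of Motif 1 was 3.796. In the list of replicate 1 alone Motif 1 had 13.8. Without peaks at tRNA genes it had 12.96, but the same 87 peaks held it. The redrawn background held it in 35 of 9780 candidates in place of 20 of 10155, so that drop reflects the draw and not the peaks left out. TATCGATA had 84.2 without GC matching, 79.5 within 50 bp and 75.2 in the stronger 50% of peaks. CACGTG no longer passed with background matched also for TSS distance (1.30), within 50 bp (1.17) or without GC matching (1.12). GATA did not pass within 50 bp (0.785) or without GC matching (0.730).

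Within the peaks, 3 of these 4 more frequent motifs were denser at the summits, and CACGTG was not (density ratio 0.829). TATCGATA was 5.70 times as dense within 50 bp as farther out (exact binomial adjusted p = 1.43e-135), Motif 1 was 2.67 times (exact adjusted p = 6.78e-07) and CAGCTG 1.31 times (exact adjusted p = 0.0283). The CAGCTG call was lost in the lists of replicates 1 and 2 alone (1.29 and 1.26), in the stronger 50% of peaks (1.14), within 25 bp (1.22) and at a global IDR of 0.001 (1.08), where Motif 1 did not pass either (1.62). The Ken consensus had a density ratio of 1.00 (289 matches within 50 bp and 1128 farther out) and did not pass. Of 32855 words of 8 bp, 449 were more frequent at summits than in flanks and 20 less frequent. The leading word was ATCGATAG, in 22.3% of summit windows and 1.48% of flanks (odds ratio 19.1, exact adjusted p = 1.50e-157), followed by TATCGATA (22.1% and 1.48%). Of the 449 words 173 contained CGATA or its complement. That core lay within 100 bp of 1529 summits, 75.3%, against 21.7% of matched candidates. At the summit of Creld on 2L, 102344 to 102404, the sequence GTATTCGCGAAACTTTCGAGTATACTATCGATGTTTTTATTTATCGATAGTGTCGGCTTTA held such words, and among the 20 strongest peaks 16 had CGATA within 100 bp and 3 had TATCGATA. The other 4 were at Sox14, Adf1, org-1 and milt.

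**Figure D3:**
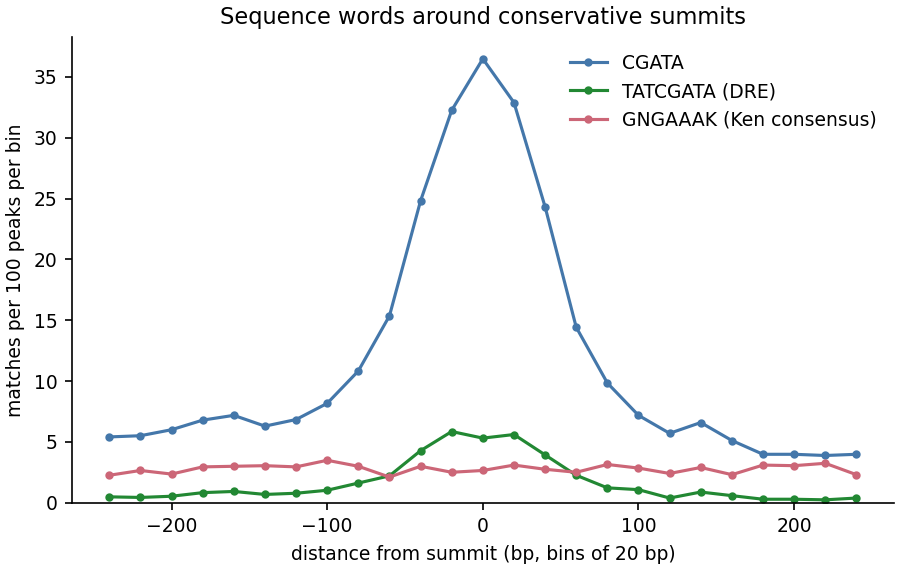
Matches per 100 conservative peaks (vertical axis) in bins of 20 bp by distance from the summit in bp (horizontal axis) for CGATA, TATCGATA and the Ken consensus GNGAAAK. CGATA peaks at 36.5 matches per 100 peaks in the central bin, whereas the Ken consensus is flat, with a density ratio of 1.00.

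The peaks fell on 2400 protein-coding genes, 19.2% of those with a candidate near a TSS, and 5 of the 27 gene lists departed from that share. Among insulator and architectural proteins, 8 of 11 were bound, 72.7% (exact 95% interval 39.0 to 94.0), with an odds ratio of 11.2 (2.98 to 42.3, Fisher exact adjusted p = 0.0012). They included BEAF-32, a boundary protein that recognises CGATA words (signal 241), Ibf1 and Ibf2, which share a promoter peak (216), and pita, a zinc finger protein (177). Ribosomal protein genes were bound in 32 of 81 cases, 39.5% (2.76, 1.77 to 4.33, exact adjusted p = 2.17e-04), led by RpL32 (842), RpS2 (555) and RpS7 (394). JAK-STAT pathway components were bound in 7 of 13 cases, 53.8% (exact 95% interval 25.1 to 80.8, odds ratio 4.91, 1.65 to 14.6, exact adjusted p = 0.0301). These were the receptor dome (390), the phosphatase Ptp61F (343), the kinase hop (314), Stat92E (285), ken, Socs36E and, named after its value was seen, Socs44A (113). The JAK-STAT call was lost in the list of replicate 2 alone (3.67, exact adjusted p = 0.106), in the stronger 50% of peaks (4.62, exact adjusted p = 0.0736), at a global IDR of 0.001 (5.40, exact adjusted p = 0.0515) and without peaks around ken (3.64, exact adjusted p = 0.131), with 0.0039 as the lowest exact adjusted p of any alternative. The insulator call was lost at a global IDR of 0.001 (4.93, exact adjusted p = 0.114), and the odds ratio ranged up to 20.5 with summits anywhere in the gene.

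Chemosensory receptor and cuticle protein genes were bound less often than other genes. Of 169 chemosensory receptor genes 0 were bound (exact 95% upper limit 2.16%, Fisher exact adjusted p = 6.45e-15), and of 110 cuticle protein genes 1 was, Cpr60D (108; odds ratio 0.038, exact adjusted p = 3.52e-08). Neuroblast and proneural genes and muscle structural genes each had 0 of 17 bound, which allows a share of up to 19.5% and did not pass (exact adjusted p = 0.193 for each). Proteasome subunits were bound in 14 of 44 cases, 31.8%, which did not pass either (1.96, exact adjusted p = 0.193), with Rpn10 (379), Prosbeta2 (263) and Prosalpha7 (233) beside Rpn6. Of the 16 BTB zinc finger factors 5 were bound, among them ken, Cp190 (145), psq (102) and dati (89.4), with an odds ratio of 1.91 (exact adjusted p = 0.573). The call passed only with the nearest TSS at any distance (5.12, exact adjusted p = 0.0145), and the odds ratio was below 1 with a TSS within 500 bp (0.948) and at a global IDR of 0.001 (0.574).

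The remaining lists did not pass, with exact adjusted p-values from 0.434, for ecdysone genes with an odds ratio of 0.335, upward. Of 16 JAK-STAT target genes 3 were bound, dome, Socs36E and crb (70.1), and of the 3 targets described as repressed by Ken 0 were, which allows a share of up to 70.8%. Bound JAK-STAT target genes were 1 of 16 in the list of replicate 2 alone (odds ratio 0.284). With the nearest TSS at any distance they were 5 of 17 (2.74), and neither setting passed. The tracheal list had 1 bound gene of 16 (emp, 75.5), the list for terminalia and genital disc 1 of 16 (tra2, 182), gap and pair-rule genes 1 of 16 (hry, 77.2), Hox genes 1 of 8 (abd-A, 74.4) and neuronal differentiation 1 of 15 (Snap25, 72.3). For Hox genes the odds ratio was 0.599, but with the nearest TSS at any distance 4 of 8 were bound (6.57, Fisher exact adjusted p = 0.0530), which did not pass. Ecdysone response and synthesis had 2 of 27, usp (245), a partner of the ecdysone receptor, and Eip75B (77.6). Notch had Su(H) (249) and mam (147) of 17. Hedgehog had boi (287) and smo (131) of 9. Wnt had Axn (180), fz3 (172), fz4 (92.1) and Wnt6 (79.9) of 19. BMP and activin had gbb (193), shn (140) and Actbeta (130) of 18, and EGFR and FGF had ed (389) and S (229) of 16. The mesoderm list had Mef2 (117) and tin (88.5) of 17, and the germ line list nanos (372) and gcl (80.0) of 12. Heat shock proteins had Hsp68 (472) and Hsp83 (242) of 13, apoptosis genes Dcp-1 (160) of 5, and GATA and endoderm 0 of 6, which allows up to 45.9%.

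**Figure D4:**
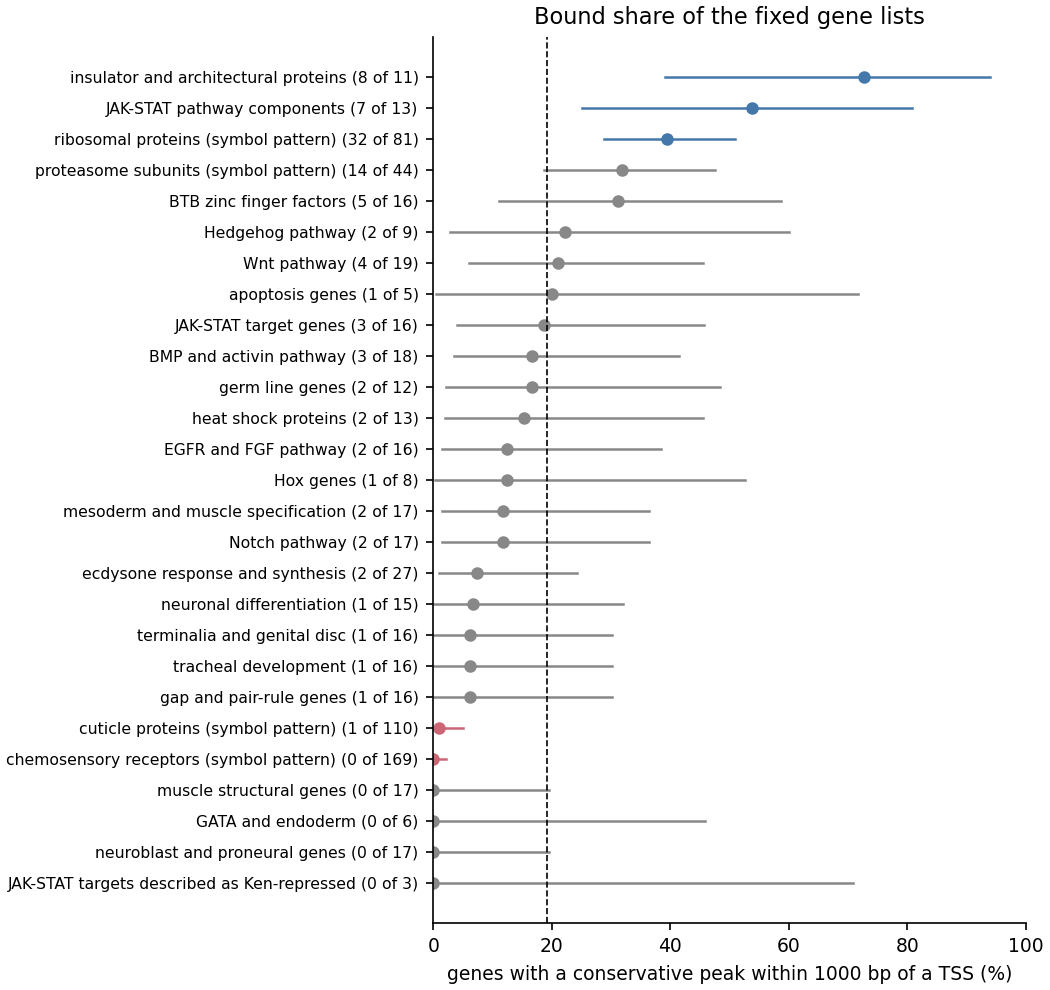
Percent of genes with a conservative peak within 1000 bp of a TSS (horizontal axis) for the 27 lists (1 line each, with counts), with exact 95% intervals as lines; blue and red mark lists above and below the rest at an adjusted p under 0.05, and the dashed line is the share of all genes with a candidate, 19.2%. Insulator proteins, JAK-STAT components and ribosomal proteins lie above it, cuticle and chemosensory genes below.

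The region of ken held more peaks than any fixed window of its length. Within 20000 bp of the gene, 2R 23850273 to 23897442, there were 14 conservative peaks, and 8 at most in the fixed windows of that length across the arms that do not touch it. Those windows, unlike this one, were not centred on a chosen gene or placed to hold the most peaks. Without peaks within 500 bp of a stronger one 11 of the 14 remained, and the other windows were not recounted in that way. Candidates that did not pass were also stronger here, 1.57 and 1.395 times the median of all in replicates 1 and 2. The strongest of the 14 conservative peaks lay outside ken, in an intron of bgcn at 23856840 to 23857103. The TSS 37 bp away was that of Pym, a gene that lies within bgcn. Its signal was 535, with 265 and 290 in the 2 replicates.

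**Figure D5:**
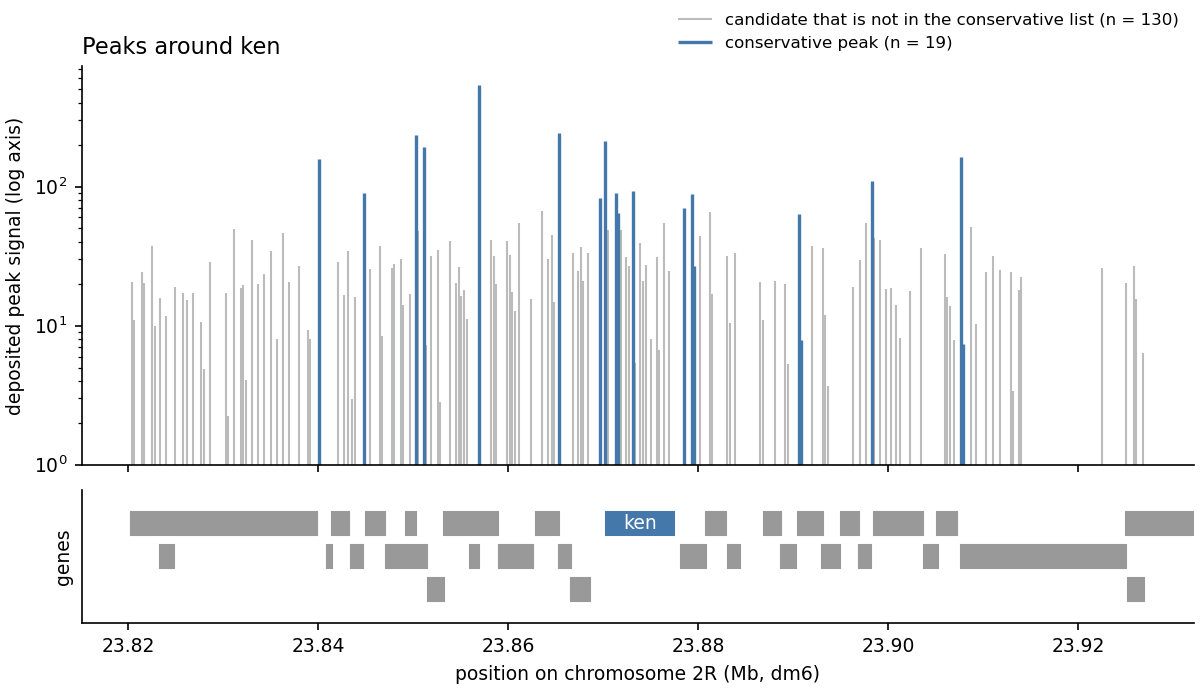
Deposited signal (vertical, log axis) of conservative peaks (blue) and other candidates (grey) by position on 2R in Mb (dm6), with protein-coding genes below and ken in blue. In the window within 20000 bp of ken lie 14 conservative peaks, and 11 when peaks within 500 bp of a stronger one are left out.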

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

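The test between the replicates was chosen after the data were seen. The peaks on scaffolds outside the main arms entered none of the comparisons and carried a signal. The conservative list held 56 of them, 2.68% of its peaks, and all 56 were on scaffolds assigned to X, spread over 48 scaffolds. Their median signal was 107, against 127 on the main arms. The thresholded list of replicate 1 held 19 (1.23%, exact 95% interval 0.74 to 1.92) and that of replicate 2 held 81 (4.45%, 3.55 to 5.50). The odds ratio between the replicates was 3.74 (Fisher exact p = 1.72e-08). Genes and sequence words were not assigned there, and no explanation was tested.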

How the results depend on the processing

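The share of summits in a 3' UTR, lower over all peaks (odds ratio 0.554), was higher over 500 bp from a TSS (2.18), and the intron share did not pass there (0.982). No other result past its threshold on the conservative list changed direction in the alternatives run, and most kept their side of the threshold. Among motifs that did not pass there, that of GAGA factor had an odds ratio of 1.38 and a density ratio of 1.25 but passed in the other direction in the stronger 50% of peaks (0.503 and 0.175) and, in density, at an IDR of 0.001 (0.195), and the cause was not tested. In the stronger 50% the sites of Grainyhead (7.54, 6 peaks) and Pho (0.528) passed. CACGTG passed in density within 25 bp (0.357). The site of Twist and Snail passed without GC matching (0.640) and without peaks around ken (0.614). In the last setting the same 30 peaks held it, and the redrawn background held it in 242 of 10060 candidates in place of 216 of 10155. The planned global IDR at or below 0.01 removed 0 peaks and tests nothing. Alternatives at an IDR of 0.001, and those that leave out neighbours of stronger peaks, peaks around ken or peaks at tRNA genes, were chosen after seeing the data. The number of peaks was 1044 in the stronger 50% and 916 at an IDR of 0.001, by construction, and 1544 and 1819 in the replicates. Shared peaks of replicates 1 and 2 were 64.5% and 56.1% with reciprocal overlap of 50%, 71.2% and 62.5% within 100 bp, and 93.05% and 96.26% against ranked candidates, as stricter and looser matching must give. The lower share of the Ken consensus did not pass in the list of replicate 2 (odds ratio 0.894, against 0.775 in that of replicate 1, and 0.716 at an IDR of 0.001), within 50 bp (0.909), without GC matching (0.900) or with background matched for GC and TSS (0.8745), and the cause was not tested. Motifs denser at summits numbered 1 in place of 3 at an IDR of 0.001, and gene lists above the rest 1 in place of 3, with fewer peaks. Words more frequent at summits numbered 200 with 6 bp, of fewer possible words, and 819 against GC-matched candidates, in place of 449. Words less frequent numbered 275 and 103 in these settings, in place of 20, so with 6 bp they outnumbered the more frequent ones, and the cause was not tested. The odds ratio of TATCGATA was 41.9 and 39.2 in the lists of replicates 1 and 2 alone and was 14.4 with background matched for GC and TSS. All 20 strongest peaks were found in each list tried, and 37 and 39 of the 50 named list members were bound in replicates 1 and 2 alone. No paired analysis was possible because the series has 1 group. Read depth is unknown, so candidates that did not pass are not shown to be unbound.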

Other observations

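The tests on the 8 added gene lists, on tRNA genes beside summits, on the signal around ken, on weak peaks beside stronger ones, on replicate differences by TSS distance, on CGATA at promoters alone and on promoter pairs at the level of peaks were chosen after the data were seen. Among the added lists, mitochondrial ribosomal proteins were bound in 26 of 67 cases, 38.8%, against 19.1% of other genes (odds ratio 2.68, 1.64 to 4.39, Fisher exact adjusted p = 0.0017). They were led by mRpL17 (signal 447), mRpL4 (388) and mRpL41 (379). Translation initiation factors were bound in 14 of 36 cases (2.68, 1.37 to 5.25, exact adjusted p = 0.0106), with eIF3f1 (499), eIF3c (441) and eIF3a (416). Cytochrome P450 genes had 3 of 72 (0.181, exact adjusted p = 0.0017) and odorant-binding proteins 1 of 49 (0.087, exact adjusted p = 0.0020). Respiratory chain and ATP synthase subunits (16 of 70), aminoacyl-tRNA synthetases (8 of 30), Mediator subunits (5 of 23) and vacuolar ATPase subunits (5 of 28) did not pass.

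Transfer RNA genes formed a class of their own. Of the 393 conservative peaks over 500 bp from a protein-coding TSS, 67 lay within 500 bp of a tRNA gene, 17.0%, against 0.13% of 130858 candidates there (odds ratio 155, 114.8 to 210, Fisher exact p = 4.17e-112). Of all 75 conservative peaks at tRNA genes, 70 had a signal in both replicates, and 63 of these were higher in replicate 1, with a median log2 difference of 0.93. Of 1840 other peaks 676 were higher in replicate 1, with a median of -0.18. Away from tRNA genes, 208 of 306 peaks over 500 bp from a TSS were higher in replicate 1, 68.0%, against 468 of 1534 nearer, 30.5% (odds ratio 4.83, Fisher exact p = 4.84e-34). CGATA lay near 14 of the 75, 18.7%, against 77.5% of other peaks.

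Peaks also favoured paired promoters. Among bound genes 53.62% had a TSS of the opposite strand within 500 bp in a divergent arrangement, against 21.95% of genes not bound (odds ratio 4.11, 3.75 to 4.51, Fisher exact p = 1.48e-194). Paired genes share peaks, so the same question was put to peaks: 41.3% of 1638 promoter peaks had TSSs of both strands within 500 bp, against 9.38% of 16019 promoter candidates (odds ratio 6.81, 6.09 to 7.61). The sets were not matched for TSS distance, as 1503 of these peaks but only 7435 of these candidates lay within 200 bp of a TSS. Part of the difference may follow from position. The signal rose with the number of CGATA words within 100 bp, from a median of 87.1 with 0 words in 502 peaks to 193 with 4 or more in 413 peaks. Spearman's rho across peaks was 0.444 (permutation p = 1e-05, the smallest possible), 0.318 with the signal of replicate 1 and 0.406 with that of replicate 2. Without peaks within 500 bp of a stronger one, rho was 0.388 across 1859 peaks. At the 1638 promoter peaks alone rho was 0.40 (permutation p = 1e-05), and at the 393 other peaks it was 0.04 (permutation p = 0.381). These values are consistent with the hypothesis that peaks with more words have a higher signal at promoters, which was found and tested on the same data.

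The abundance of CGATA words was set against 3 technical accounts. Promoter location and base composition alone would leave little enrichment against background matched for both, but the lower 95% bound of the odds ratio was 7.13. If ribosomal protein genes were all of high transcription, transcription level alone would give bound and unbound ones the same share. CGATA was within 200 bp of a TSS in 31 of 32 bound and 29 of 49 unbound ones, an odds ratio of 21.38 (2.69 to 170, Fisher exact p = 7.87e-05). Transcription was not measured and the list was taken by symbol pattern, so this test cannot set the account aside. Retrieval of highly transcribed genes whatever the antigen predicted peaks at tRNA genes at least as often as at protein-coding genes. That prediction was met: 35.5% of 290 against 15.4% had them (3.023, 2.37 to 3.86, too narrow because clustered genes share peaks). Ribosomal protein genes were also bound more often than other genes in the conservative list (odds ratio 2.76, 1.77 to 4.33). A further condition, CGATA at the tRNA peaks, was added after the values were seen, and these peaks mostly lacked CGATA. The test therefore cannot decide whether retrieval accounts for the words. With no control library, retrieval and transcription level stay open beside Ken itself or a partner such as BEAF-32 or DREF, and no biological explanation was tested.

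The density of peaks around ken was weighed against 3 accounts. If the window only held many promoters, its peaks would be at TSSs as often as others: 57.14% were, against 80.8% elsewhere (Fisher exact p = 0.0373). By the condition set beforehand, that share went against this account. A further condition was added after the values were seen. Without 3 peaks beside a stronger one, 7 of 11 were at TSSs (63.6% against 80.7%, exact p = 0.240). CGATA lay near 35.71% of the 14 peaks against 75.56% elsewhere (exact p = 0.0019) and near 5 of those 11 (exact p = 0.0164), unlike most promoter peaks, but among their promoter peaks alone it lay near 5 of 7 against 88.6% (exact p = 0.187). The account of many promoters stays open only under the added condition. Extra copies of the locus in the transgenic strain would also raise candidates that did not pass. Their median signal in the window was 1.57 times the genome's median in replicate 1 and 1.395 times in replicate 2, at the 99.85 and 99.42 percentiles of windows of that length, so extra copies are a candidate explanation, found on the same data, but the labels name an insertion targeting ken without saying whether it adds a copy. Binding at the Ken consensus could not be decided: 35.71% of the 14 peaks had it against 23.2% elsewhere (exact p = 0.336).

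Of 90 conservative peaks with a signal under 20, 88 (97.78%) had a stronger conservative peak within 500 bp, at a median of 203 bp, against 88 of the other 1997 (4.41%). A candidate explanation is that the weak entries are further matches of a stronger neighbour, found and tested on the same data.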
